A study of Mus musculus with 72 samples.

How the data were processed

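RNA sequencing of liver and placenta from mouse fetuses at embryonic day 14.5 was read from the deposited files, with no paper at hand. The labels gave 72 libraries in 12 groups of 6 (3 males and 3 females each): in each tissue, culture control, culture antioxidant and an in vivo group in one series, and vitrified control, vitrified antioxidant and an in vivo group in another. Per the labels' protocols, embryos were grown in G series media, day 4 blastocysts were transferred to recipients, tissue was taken 10 days later, RNA was isolated with Qiagen RNeasy Plus, and libraries from 1 ug of total RNA were sequenced on an Illumina HiSeq.

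The tools FastQC, Trim Galore, STAR, featureCounts and DESeq2 and the builds GRCm38 and mm10 were named, without versions, roles or options, per the submitters' processing notes. The authors' 14 deposited comparison tables were read, and no values per library were used here. The deposited tables had no header line, and their columns were identified from their values and from the tool named: the mean normalized count, the log2 fold change, its standard error, the Wald score, the p-value and the adjusted p-value of 27179 genes. The deposited mean normalized count was read as a signal averaged over all libraries of the comparison after division by size factors, a reading that no header or label states. Of the NCBI gene numbers, 25275 (93.0%) were matched to a symbol and to GRCm38 coordinates in the annotation supplied. The deposited log2 fold changes were shrunken by a normal prior, which the relation of the Wald score to the fold change and its error showed, and its width was recovered from the largest standard error of each table. Of the 14 tables, 12 held the second-named group of their file over the first-named one and 2, the cross-series control tables, the opposite. The sign was set from group means and the 2 were turned.

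Group means were computed from the deposited tables: each in vivo, control and antioxidant group appears in several tables, and single-read genes gave the size factors on which each table had been normalized. Group mean totals of normalized reads, in units of 1e6, were 20.5 to 28.9, and size factors ran from 0.791 to 1.53. The median standard error of the fold change without the prior was 0.10 to 0.19. In vivo means differ slightly between tables because each was normalized separately. No count model was refitted, since no counts per library were used.

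The main result of each comparison was the authors' adjusted p-value under 0.05. Genes without an adjusted p-value were not called, and those with a Wald score but no p-value are referred to as outliers, the reason DESeq2 has for leaving out such a p. The rule for genes named in the text, written before the data were examined, was as follows. Each comparison gave the 10 rising and 10 falling genes of smallest adjusted p with a mean of 20 or more, and up to 3 called members of each fixed list by absolute Wald score. Where fewer than 5 genes passed, it gave the called genes and otherwise 3 of smallest unadjusted p as values that did not pass. Sex-linked genes and Igf2, H19, Slc2a1, Nqo1, Hmox1 and Cpt1a were followed in all comparisons. The text names a part of these genes.

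The 33 gene lists were fixed at the same time, 28 of them tested in liver and 31 in placenta (413 tests). They covered metabolism and stress (antioxidant and glutathione enzymes, fatty acid oxidation and carnitine, lipoate-dependent complexes, oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, glycolysis, hypoxia response, cholesterol synthesis, fatty acid and triglyceride synthesis, unfolded protein response, immediate early and heat shock genes, p53 targets and apoptosis, cell cycle, interferon response), imprinted genes, DNA methylation and chromatin regulators, sex-linked control genes, cells of the liver and blood (erythroid, megakaryocyte and platelet, neutrophil and mast, macrophage, lymphoid and natural killer, endothelium, mesenchyme and matrix, hepatocyte and visceral endoderm, hepatic enzymes, cholangiocyte) and the placenta (hormones and junctional zone, labyrinth trophoblast, nutrient transporters, decidua and uterine tissue, preeclampsia and angiogenic factors). Each was tested with cameraPR of limma 3.58.1 on Wald scores with a preset correlation of 0.01, adjusted within a comparison by Benjamini-Hochberg. A correlation estimated from the libraries could not be computed, and a preset of 0.05 was the alternative. Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Hspa1a and Hspa1b, and the Serpina1, Prl2c and granzyme families share reads, so their levels are uncertain.

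Differences between series were tested per gene as the difference of fold changes over its standard error, with Benjamini-Hochberg adjustment, and overlaps were set beside independent lists and beside 100 simulated sets with no effect that shared the in vivo group (seed 20240). The slope of the antioxidant change on the gap to in vivo was computed with the error covariance of the shared control group subtracted. Trends of Wald scores with transcript length or GC content of the longest transcript were removed by lowess (span 0.3). The difference test was tried on simulated tables with 200 planted genes. For the antioxidant effect, differences were planted before shrinkage. For the difference from in vivo they were planted on the deposited scale, and 85% of differences of 1 were recovered in liver and 82% in placenta, and 35.5% and 22.5% of differences of 0.5. On simulated data with independent genes, at an unadjusted p under 0.05, the list test called 5 of 100 lists with no shift and 81 with a shift of 0.5. That does not give the rate of false calls for lists whose genes vary together. With error variances known exactly, the slope came back as 0.003 and 0.501 for 0 and 0.5 planted in liver. Alternatives were an adjusted p under 0.01, an absolute log2 fold change of 1 or more, minimum means of 10 and 100, an empirical null, rank versions of list tests and removal of the trends. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3.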

Results

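The series measured messenger RNA in liver and placenta of mouse fetuses at embryonic day 14.5. The fetuses were C57BL/6 x CBA F1 and differed in how they had spent the days before implantation. In the culture series, embryos grew to the blastocyst stage in a sequential embryo medium without additions (culture control) or with a mixture of alpha-lipoic acid, N-acetyl-L-cysteine and L-carnitine (culture antioxidant). Alpha-lipoic acid is a cofactor of mitochondrial dehydrogenases, N-acetyl-L-cysteine supplies cysteine for glutathione, and L-carnitine carries fatty acids into mitochondria. In the vitrification series, cultured embryos were vitrified, that is, cooled to a glass without ice crystals, and warmed without antioxidants (vitrified control) or with them (vitrified antioxidant). Each series had an in vivo group of its own, made from blastocysts flushed on day 4. The labels listed 72 libraries in 12 groups of 6, with 3 males and 3 females per group. Nothing in the labels said which fetuses shared a dam, so the p-values of single genes measure the spread between these libraries. Those of gene lists measure the spread of Wald scores across genes, with the correlation between genes preset and not measured. Group mean totals of normalized reads, in units of 1e6, ran from 20.5 to 28.9, and the size factors recovered from single-read levels ran from 0.791 to 1.53, with the highest up to 1.88 times the lowest within a group. Totals after scaling do not compare the depth of sequencing between groups. Below, values from the authors' deposited tables are given as log2 fold change ± standard error of the first-named group over the second, and group means are normalized read counts computed from those tables.

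**Figure D1:**
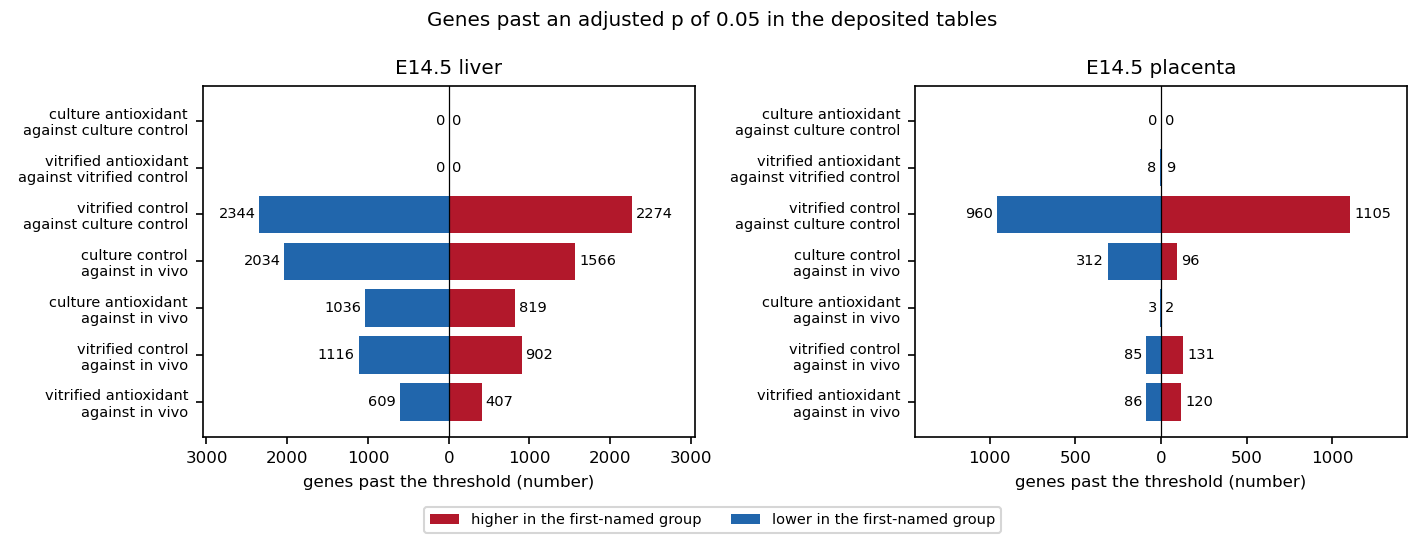
Number of genes past an adjusted p of 0.05 in each of the 14 deposited comparisons, liver on the left and placenta on the right, with genes higher in the first-named group drawn to the right of 0 and lower genes to the left. Liver had 0 genes past the threshold between antioxidant and control groups and up to 4618 between other groups, and placenta had 0 to 17 and up to 2065.

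The counts depended on the null used. Under an empirical null, which rescales the Wald scores of a table by their own spread, liver kept 1 gene between vitrified and culture controls and, against in vivo, 148 for the culture control, 4 for the culture antioxidant, 3 for the vitrified control and 1 for the vitrified antioxidant group. Placenta kept 1 for antioxidants at vitrification, 1 between controls and, against in vivo, 32 for the vitrified control and 0 for the other groups. The spread used for rescaling includes any real shift across many genes, so such a shift is removed with it. Between the liver controls that spread was 2.42, and 30.0% of genes had an unadjusted p under 0.05 by the Wald test. The lower counts therefore cannot tell false calls from a broad real shift.

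The first question was whether antioxidants given to the embryo altered the fetal liver. In the culture series no single transcript passed, but fixed gene groups moved by small amounts in a common direction. Nuclear-encoded subunits of oxidative phosphorylation, the respiratory chain and ATP synthase, fell with antioxidants (median log2 fold change -0.09 over 52 members, 49 of them below 0; cameraPR adjusted p = 4.7e-08). Antioxidant and glutathione enzymes fell as well (median -0.09, 39 of 47 members below 0; adjusted p = 1.05e-05). Genes of the hypoxia response rose (22 of 28 members above 0; adjusted p = 2.04e-04), as did glycolysis and glucose transport (21 of 25 above 0; adjusted p = 3.92e-04) and markers of cholangiocytes, the bile duct cells (11 of 12 above 0; adjusted p = 3.92e-04). Immediate early and heat shock genes had an adjusted p = 0.0116 for a rise, which became an adjusted p = 0.0951 with a preset correlation of 0.05. Cytosolic ribosomal proteins fell (33 of 41 below 0; adjusted p = 1.67e-04). Fold changes in this comparison rose with transcript length (Spearman rho = 0.33 across 13361 genes, which are not independent replicates). Removing that trend ended the ribosomal call (adjusted p = 0.402). It also ended falls of mitochondrially encoded genes (adjusted p = 0.0126, then 0.99) and the interferon response (0.00604, then 0.0626). Cell type markers moved in the same comparison: hepatocyte genes fell (adjusted p = 0.00438, and adjusted p = 0.0724 with a correlation of 0.05), neutrophil and mast cell genes fell (0.0172, then 0.0951) and mesenchyme rose (0.0215, then 0.126). Without the length trend these 3 lists lost their calls too (adjusted p = 0.0753, 0.57 and 0.22). DESeq2 gave 0 genes past the threshold and 835 (4.07%) at an unadjusted p under 0.05, a smaller share than chance alone gives. The smallest adjusted p was 0.791. Among the genes with the smallest p, the authors' deposited table listed the replication fork enzyme Smarcal1 at 0.24 ± 0.06, the lysophospholipid acyltransferase Lpcat1 at 0.43 ± 0.11 and Fam110c at -0.47 ± 0.12.

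In the vitrification series 11 lists passed, 8 of them for a rise, and several of the gene groups above ran the other way. The lists given here are among those that rose. Oxidative phosphorylation subunits rose with antioxidants (median 0.10, 49 of 52 members above 0; adjusted p = 3.28e-10). Antioxidant and glutathione enzymes rose (42 of 47 above 0; adjusted p = 5.24e-07), as did cytosolic ribosomal proteins (median 0.13, 35 of 41 above 0; adjusted p = 7.33e-07) and cell cycle genes (31 of 38 above 0; adjusted p = 5.78e-05). Here fold changes fell with transcript length (rho = -0.31), and these 4 calls stayed past the threshold after removal of that trend. Megakaryocyte and platelet genes (14 of 16 above 0; adjusted p = 0.00192) and cholangiocyte genes (11 of 12 above 0; adjusted p = 0.0109) rose too, as did macrophage genes (adjusted p = 0.021, and adjusted p = 0.15 with a correlation of 0.05 and 0.191 without the length trend). The difference of each list between the 2 series was not tested. DESeq2 again gave 0 genes past the threshold. At an unadjusted p under 0.05 there were 669 (3.23%), also a smaller share than chance alone gives. The closest were the predicted gene Gm3716 (0.46 ± 0.10, adjusted p = 0.162), Pdk4, a kinase that restrains pyruvate oxidation (-0.46 ± 0.11, adjusted p = 0.386), and the homeodomain protein Hopx (0.35 ± 0.09, adjusted p = 0.883) in the authors' deposited table. The genes set for reporting in every comparison gave, in the authors' deposited tables for culture and vitrification in turn, 0.10 ± 0.09 and -0.08 ± 0.07 for the growth factor Igf2, and -0.09 ± 0.10 and 0.15 ± 0.10 for the NRF2 target Nqo1. Heme oxygenase Hmox1 stood at -0.02 ± 0.12 and 0.04 ± 0.10, and Cpt1a, the carnitine palmitoyltransferase of fatty acid oxidation, at 0.01 ± 0.11 and 0.02 ± 0.09 in the authors' deposited tables. None of these 4 passed.

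Placenta gave 17 genes past the threshold for antioxidants at vitrification (9 higher, 8 lower) and 0 for antioxidants in culture. The clearest was Trpv6, the epithelial channel for calcium uptake (chromosome 6, 41620619 to 41636405, GRCm38), with group means of 212 against 61.8 and 0.84 ± 0.14 in the authors' deposited table (adjusted p = 4.28e-05). The maternally expressed imprinted RNA Meg3 rose (0.61 ± 0.14, means 494 against 202), as did the Wnt deacylase Notum (0.56 ± 0.13), the urea transporter Slc14a1 (0.59 ± 0.14) and the hindlimb and pituitary factor Pitx1 (0.56 ± 0.14), per the authors' deposited table. Among the 8 that fell were the glycolytic enzyme Tpi1 (-0.27 ± 0.06), the connexin Gjb5 (-0.44 ± 0.10), the calcium sensor Hpcal1 (-0.43 ± 0.09) and Edem2, which trims glycans of misfolded glycoproteins (-0.36 ± 0.08), again from the authors' deposited table. As groups, 10 lists passed, 3 of them for a rise, and not all that fell are given here. Ribosomal proteins fell (median -0.16, 31 of 41 below 0, 9 past the threshold adjusted over the list alone, cameraPR adjusted p = 1.56e-12). Placental hormones and junctional zone genes fell too (median -0.14, 43 of 51 below 0; adjusted p = 1.88e-07). Interferon response genes rose (median 0.14, 30 of 35 above 0; adjusted p = 1.75e-07), and all 10 measured mitochondrially encoded genes lay above 0 (median 0.23, 5 past the threshold adjusted over the list alone; adjusted p = 1.88e-07). Markers of other cells moved as well: hepatocyte and visceral endoderm genes rose (33 of 34 above 0; adjusted p = 2.57e-05) and macrophage genes fell (20 of 24 below 0; adjusted p = 5.54e-05). After removal of the trend with transcript length, Aifm3, Wsb1, Pitx1 and the calcium channel Cacna1c no longer passed.

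With antioxidants in culture, the placental groups shifted without a single gene passing. All 34 markers of hepatocyte and visceral endoderm, which the yolk sac also expresses, lay below 0 (median -0.18; adjusted p = 4.24e-13). As for every list, that p does not measure the spread between placentas, and markers of the same tissue can vary together. How much yolk sac the placentas carried was not measured. Interferon response genes (median 0.12; adjusted p = 3.62e-04), lymphoid and natural killer genes (0.19; 2.88e-04) and oxidative phosphorylation (0.10; 4.25e-04) rose. Placental hormones fell (median -0.10; adjusted p = 4.25e-04). Cell cycle genes rose (32 of 37 above 0; adjusted p = 0.00106), and endothelial genes fell with an adjusted p = 0.0152, which became an adjusted p = 0.0988 with a correlation of 0.05. Decidual genes had a median of 0.21 and an adjusted p = 0.00388, which became an adjusted p = 0.0507 with a correlation of 0.05. DESeq2 gave 0 genes past the threshold, with a smallest adjusted p of 0.999. At an unadjusted p under 0.05 there were 455 (2.11%), a smaller share than chance alone gives. Closest by unadjusted p were the enoyl reductase Tecr (-0.33 ± 0.09), the DNA sensor Aim2 (0.79 ± 0.23) and the meiotic protein Kash5 (0.69 ± 0.20) in the authors' deposited table. Igf2 stood at -0.19 ± 0.14 here and 0.10 ± 0.09 in the vitrification series, and the glucose transporter Slc2a1 at -0.03 ± 0.13 and -0.16 ± 0.09, in the authors' deposited tables.

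Against in vivo, livers from cultured embryos held fewer transcripts of lipid synthesis and cell cycle lists and more from the mitochondrial genome. Gpam, the first enzyme of triglyceride synthesis (chromosome 19, 55067635 to 55127319, GRCm38), had means of 395 against 1278 and -1.51 ± 0.14 in the authors' deposited table (adjusted p = 2.23e-22). Fatty acid synthase Fasn (-1.12 ± 0.17) and the desaturase Fads2 (-1.01 ± 0.13) fell with it in the authors' deposited table. Of 24 genes of fatty acid and triglyceride synthesis, 10 fell and 1 rose (10 and 2 adjusted over the list alone; cameraPR adjusted p = 0.00128). Cholesterol synthesis fell in 13 of 25 members and rose in 0 (13 and 0 adjusted over the list alone; adjusted p = 1.28e-04), led by Dhcr24, its last reductase (-0.56 ± 0.08), the sterol carrier Stard4 (-0.71 ± 0.11) and Pcsk9, which degrades the LDL receptor (-0.55 ± 0.09), in the authors' deposited table. In the cell cycle list 12 of 38 fell and 3 rose (13 and 4 adjusted over the list alone; adjusted p = 5.28e-04), among them the replicative helicase subunits Mcm2 (-0.70 ± 0.09) and Mcm5 (-0.61 ± 0.08) and cyclin Ccne2 (-1.29 ± 0.17), as the authors' deposited table listed them. Erythroid genes fell in 14 of 33 members (16 fell and 1 rose adjusted over the list alone; adjusted p = 8.58e-04), such as the band 3 anion exchanger Slc4a1 (-0.56 ± 0.09) and the heme enzyme Cpox (-0.42 ± 0.07), from the authors' deposited table.

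Mitochondrially encoded transcripts rose in 7 of 12 measured members and fell in 0 (7 and 0 adjusted over the list alone; median 0.85; adjusted p = 6.68e-08). The complex I subunit mt-Nd4 had means of 40870 against 17355 and 1.05 ± 0.16, and the cytochrome b gene mt-Cytb had 0.99 ± 0.16, in the authors' deposited table. The imprinted noncoding RNAs Meg3 (chromosome 12, 109540996 to 109571729, GRCm38) and Mirg, neighbours on the maternal allele, rose by 1.31 ± 0.22 and 1.11 ± 0.18 per the authors' deposited table. The imprinted list as a whole gave 11 up and 8 down of 54 and did not pass (adjusted p = 0.0861), and neither H19 (0.01 ± 0.11) nor Igf2 (-0.07 ± 0.09) passed in the authors' deposited table. The smallest p-values belonged to genes of other functions. The membrane protein Lmbrd2 (-1.94 ± 0.15, adjusted p = 5.94e-33), the hedgehog receptor Ptch1 (-1.93 ± 0.16, means 90.3 against 424) and the splicing-factor kinase Uhmk1 (-2.04 ± 0.18) led the authors' deposited table. The glucose transporter Slc2a1 fell (-0.53 ± 0.11, adjusted p = 3.86e-05), and catalase Cat rose (0.31 ± 0.06) in the authors' deposited table. In all, 3600 genes passed (1566 higher, 2034 lower). Of the 131 with an absolute log2 fold change of 1 or more, 13 were higher. An empirical null left 148, of which 15 were higher. Fold changes fell with transcript length (rho = -0.29), a trend that the short mitochondrial and long lipid synthesis transcripts lie along, and both list calls held after its removal (adjusted p = 5.25e-04 and 0.0115). Fatty acid oxidation (7 of 30 down; adjusted p = 0.00937, which became an adjusted p = 0.0998 with a correlation of 0.05) and glycolysis (3 of 25 down; 0.0375, then 0.194, and 0.0707 without the length trend) passed less firmly.

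Livers of the culture antioxidant group differed from the same in vivo livers at 1855 genes (819 higher, 1036 lower). Mitochondrially encoded genes (adjusted p = 0.0532) and cholangiocyte markers (adjusted p = 0.11) did not pass as lists here, but this depended on the setting. The mitochondrial list passed for a rise by ranks (adjusted p = 0.0206), with a background of means of 10 or more (0.0361) and with outlier genes (0.0477), and the cholangiocyte list for a fall with outlier genes (0.0166). Of the 12 cholangiocyte markers, 5 had no p here as outliers, and 6 had none for the culture control against in vivo. Fatty acid and triglyceride synthesis (4 of 24 down; adjusted p = 0.0697) and glycolysis (adjusted p = 0.473) did not pass. Cell cycle genes fell in 9 of 38 members (12 down and 2 up adjusted over the list alone; adjusted p = 6.23e-05), including the helicase subunits Mcm4 (-0.27 ± 0.06) and Mcm6 (-0.45 ± 0.10) and Ccne2 (-0.83 ± 0.14), in the authors' deposited table. Cholesterol synthesis fell in 4 of 25 (5 adjusted over the list alone; adjusted p = 3.93e-04), and fatty acid oxidation in 4 of 30 (4 adjusted over the list alone; adjusted p = 3.93e-04), with the beta-oxidation subunit Hadha at -0.30 ± 0.09 in the authors' deposited table. Meg3 (1.27 ± 0.18), Mirg (1.00 ± 0.18), the Argonaute protein Ago2 (-1.09 ± 0.13) and Uhmk1 (-1.48 ± 0.16) were among the strongest in the authors' deposited table. Gpam was at -0.74 ± 0.19 and Fasn at -0.55 ± 0.19 there, and Slc2a1 at -0.21 ± 0.15 did not pass, per the authors' deposited table. Erythroid genes (8 of 33 down; adjusted p = 0.00505) lost their call with a correlation of 0.05 (adjusted p = 0.112), as did hepatic amino acid, glucose and detoxification enzymes (adjusted p = 0.00543, then 0.146).

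**Figure D2:**
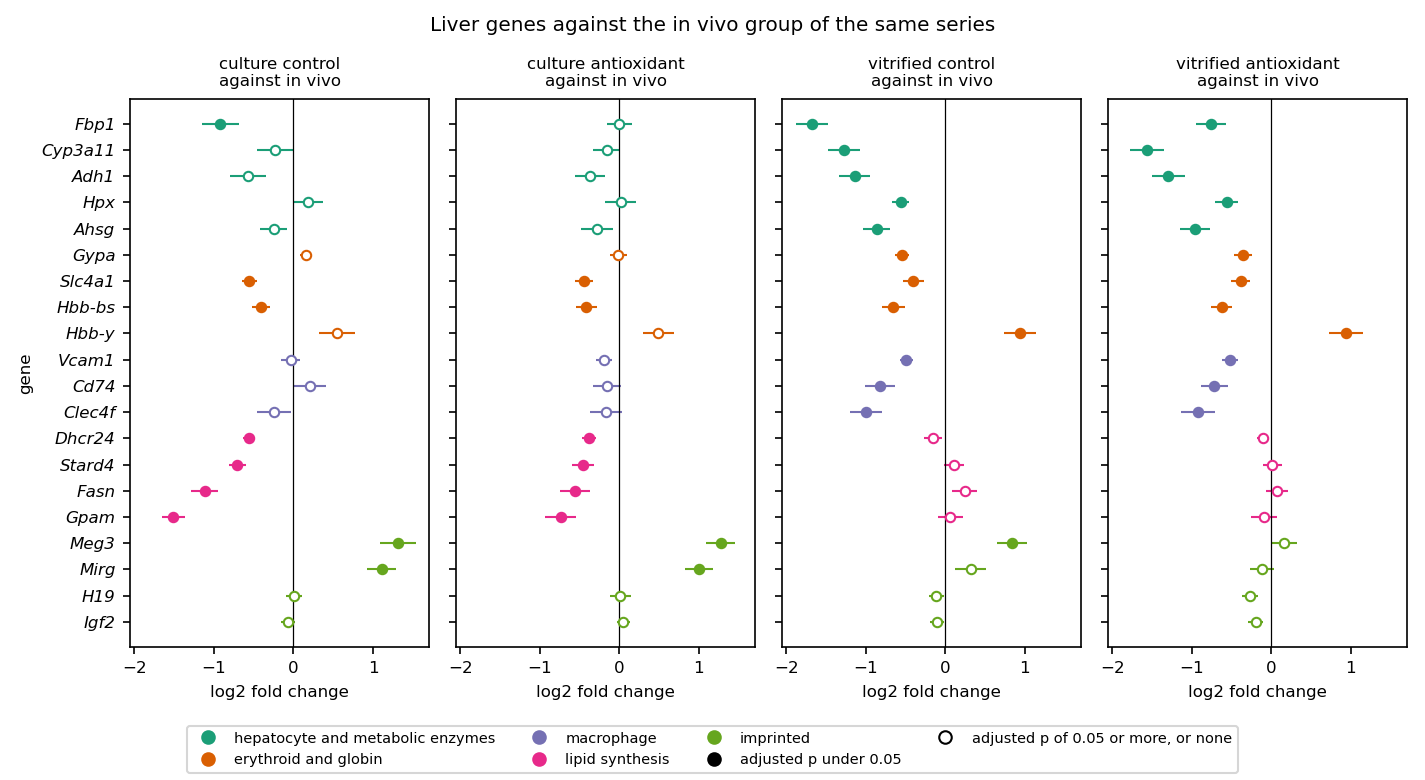
Deposited log2 fold change (x axis) of 20 liver genes in each of the 4 comparisons against the in vivo group of the same series, with bars of 1 standard error; filled points have an adjusted p under 0.05 and open points do not. Lipid synthesis genes such as Gpam (-1.51) lie below 0 in the culture series, and hepatocyte genes such as Cyp3a11 (-1.27 and -1.56) lie below 0 in the vitrification series.

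Livers from vitrified embryos held fewer transcripts of the hepatocyte, erythroid and macrophage lists than in vivo livers. Fbp1, the gluconeogenic fructose bisphosphatase (chromosome 13, 62864753 to 62888298, GRCm38), had means of 25.7 against 338 and -1.68 ± 0.20 in the authors' deposited table (adjusted p = 9.19e-13). The steroid and drug oxidase Cyp3a11 (-1.27 ± 0.20), alcohol dehydrogenase Adh1 (-1.14 ± 0.20) and the plasma protein gene Itih4 (-1.39 ± 0.17) fell with it in the authors' deposited table. Of 34 hepatocyte genes 19 fell and 0 rose (19 and 0 adjusted over the list alone; median -0.47; cameraPR adjusted p = 1.13e-17), and of 44 hepatic enzyme genes 14 fell and 0 rose (19 and 0 adjusted over the list alone; adjusted p = 2.19e-13). Macrophage genes fell in 19 of 24 members (20 adjusted over the list alone; median -0.49; adjusted p = 2.21e-18), among them the adhesion molecule Vcam1 of erythroblastic islands (-0.49 ± 0.08), the antigen-presentation chain Cd74 (-0.83 ± 0.19) and the signalling adaptor Tyrobp (-0.51 ± 0.10), in the authors' deposited table. Erythroid genes fell in 19 of 33 members and rose in 2 (21 and 2 adjusted over the list alone; adjusted p = 9.27e-18). These included glycophorin Gypa (-0.54 ± 0.09) and the heme enzymes Hmbs (-0.52 ± 0.08) and Urod (-0.56 ± 0.09) in the authors' deposited table. Among globins, embryonic Hbb-y rose (0.94 ± 0.20, means 16718 against 4386) while adult Hbb-bs fell (-0.66 ± 0.14, means 118220 against 201908) in the authors' deposited table; Hbb-bs shares reads with a near-identical copy and its level is uncertain.

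The fall reached proliferation and the nuclear-encoded part of the respiratory chain as well. Cell cycle genes fell in 18 of 38 members (26 down and 2 up adjusted over the list alone; adjusted p = 8.25e-20), such as thymidylate synthase Tyms (-0.33 ± 0.05) and the ribonucleotide reductase subunit Rrm1 (-0.41 ± 0.06) in the authors' deposited table. All 52 oxidative phosphorylation subunits lay below 0, 15 of them past the threshold (22 adjusted over the list alone; adjusted p = 7.13e-15). Antioxidant and glutathione enzymes fell in 18 of 46 members (20 adjusted over the list alone; adjusted p = 5.24e-12), including the microsomal glutathione transferase Mgst3 (-0.66 ± 0.12) and glutathione synthetase Gss (-0.33 ± 0.06) in the authors' deposited table, and Hmox1 had -0.40 ± 0.13 (adjusted p = 0.0183). Fatty acid oxidation fell in 12 of 30 (14 adjusted over the list alone; adjusted p = 2.71e-10), with Acadvl, the first dehydrogenase for very long chains, at -0.32 ± 0.06 in the authors' deposited table. Lymphoid genes fell in 7 of 27 (adjusted p = 1.34e-04), led by the pre-B receptor chain Vpreb1 (-1.13 ± 0.20) and Cd19 (-0.96 ± 0.20), and unfolded protein response genes in 5 of 29 (adjusted p = 0.00189), the gene values again from the authors' deposited table.

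Other groups rose. Mesenchyme and extracellular matrix genes rose in 6 of 26 members and fell in 1 (7 and 1 adjusted over the list alone; median 0.31; adjusted p = 7.36e-07), for example collagen Col1a1 (0.75 ± 0.18) and the pericyte receptor Pdgfrb (0.50 ± 0.09) in the authors' deposited table. Mitochondrially encoded genes, opposite to the nuclear-encoded subunits, rose in 2 of 12 members (7 adjusted over the list alone; median 0.32; adjusted p = 4.41e-04). Endothelial genes rose in 3 of 22 (adjusted p = 4.41e-04), and megakaryocyte and platelet genes rose in 1 of 16 (adjusted p = 0.0293, and adjusted p = 0.0884 with a correlation of 0.05). Imprinted genes rose in 13 of 54 and fell in 0 (19 and 0 adjusted over the list alone; adjusted p = 6.56e-06), including the paternally expressed Peg10 (0.61 ± 0.12) and Peg13 (0.58 ± 0.10) and the transporter Slc22a3 (0.66 ± 0.12), in the authors' deposited table. The de novo DNA methyltransferases Dnmt3a and Dnmt3b were both at 0.43 ± 0.09 in the authors' deposited table, within a list of chromatin regulators (6 of 34 up; adjusted p = 0.00964) that lost its call with a correlation of 0.05 (adjusted p = 0.0837) and without the length trend (adjusted p = 0.246). In all, 2018 genes passed (902 higher, 1116 lower). Fold changes rose with transcript length (rho = 0.38), and 57.5% of the called genes with a transcript stayed called in the same direction after its removal. Without the trend 1348 genes passed, 468 of them higher. At an absolute log2 fold change of 1 or more, 1 of 21 was higher. That removal ended the calls for ribosomal proteins (adjusted p = 9.41e-06, then 0.22) and for neutrophil and mast cells (0.00123, then 0.22).

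With antioxidants at vitrification, 1016 liver genes differed from the same in vivo livers (407 higher, 609 lower), and hepatocyte genes led again. Without the length trend 238 of 801 were higher. Cyp3a11 (chromosome 5, 145854607 to 145879854, GRCm38) had means of 58.3 against 349 and -1.56 ± 0.21 (adjusted p = 1.29e-09), Adh1 -1.29 ± 0.21 and transferrin Trf -0.73 ± 0.15 in the authors' deposited table. Hepatocyte genes fell in 20 of 34 members (23 down and 1 up adjusted over the list alone; adjusted p = 1.24e-23), and fatty acid oxidation in 11 of 30 (15 adjusted over the list alone; adjusted p = 1.41e-16), including the ketone body enzyme Hmgcs2 (-0.69 ± 0.15) in the authors' deposited table. Erythroid genes fell in 14 and rose in 2 of 33 (23 and 2 adjusted over the list alone; adjusted p = 1.83e-14), macrophage genes fell in 10 of 24 (15 adjusted over the list alone; adjusted p = 2.3e-14), and neutrophil genes in 7 of 22 (adjusted p = 4.86e-06), such as Lcn2 (-0.64 ± 0.17) in the authors' deposited table. Megakaryocyte and platelet genes rose in 3 of 16, with all 16 above 0 (adjusted p = 9.44e-07), among them the thrombopoietin receptor Mpl (0.55 ± 0.16) in the authors' deposited table. Mesenchyme and matrix genes rose in 3 of 26 and fell in 1 (5 and 1 adjusted over the list alone; adjusted p = 2.33e-07), lymphoid genes fell in 4 of 26 (adjusted p = 8.03e-05), and cell cycle genes fell in 5 of 38 (7 adjusted over the list alone; adjusted p = 6.32e-10). Oxidative phosphorylation had 0 members past the threshold (median -0.10; adjusted p = 1.27e-05), while mitochondrially encoded genes rose in 2 of 11 (6 adjusted over the list alone; adjusted p = 1.31e-04). Hbb-y (0.94 ± 0.21) and Mgst3 (-0.52 ± 0.09) passed as they had without antioxidants, whereas Meg3 stood at 0.84 ± 0.19 in the control and 0.16 ± 0.15 here in the authors' deposited tables. The imprinted list (7 of 54 up; adjusted p = 0.00354) lost its call with a correlation of 0.05 (adjusted p = 0.08) and with the length trend removed (adjusted p = 0.0578).

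Placentas of the culture control carried fewer transcripts of the decidua, the maternal tissue they sit on, than in vivo placentas. Decidual genes fell in 7 of 25 members and rose in 0 (14 and 1 adjusted over the list alone; median -0.64; cameraPR adjusted p = 2.97e-07). The estrogen receptor Esr1 (-1.15 ± 0.25), the matrix protease Adamts5 (-1.05 ± 0.25) and the prostaglandin D synthase Ptgds (-1.02 ± 0.25) were the named members in the authors' deposited table. Tdo2, which degrades tryptophan and is made by decidual cells (chromosome 3, 81958412 to 81975728, GRCm38), had means of 10.5 against 62.2 and -1.54 ± 0.25 in the authors' deposited table (adjusted p = 4.49e-06). The sterol carrier Stard4 (-0.88 ± 0.17), the gap junction protein Gja1 (-1.02 ± 0.19) and the activin subunit Inhba (-1.11 ± 0.25) fell too, and smooth muscle actin Actg2 rose (0.97 ± 0.21), in the authors' deposited table. Macrophage genes fell in 2 of 23 members (adjusted p = 0.00216), the lysosomal enzymes Ctss (-1.04 ± 0.25) and Lyz2 (-0.93 ± 0.25) in the authors' deposited table. Hepatocyte and visceral endoderm genes had 33 of 34 members below 0 (adjusted p = 0.00551, and adjusted p = 0.0956 with a correlation of 0.05). Oxidative phosphorylation rose as a group with 0 members passing (median 0.15; adjusted p = 8.8e-05). In all, 408 genes passed (96 higher, 312 lower). Fold changes fell with transcript length (rho = -0.31), and removing the trend kept the decidual call (adjusted p = 4.42e-08) but ended that of mitochondrially encoded genes (adjusted p = 0.00748, then 0.163). Placental hormones had an adjusted p = 0.0473 for a rise, which became an adjusted p = 0.3 with a correlation of 0.05 and 0.671 without the length trend. Igf2 (-0.02 ± 0.13), H19 (0.04 ± 0.09) and Slc2a1 (-0.25 ± 0.15) did not pass in the authors' deposited table.

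With antioxidants in culture, 5 placental genes differed from in vivo. The median standard error without the prior was 0.1876 here, against 0.1445 for the culture control against in vivo. The 2 counts of genes therefore do not compare the size of the departures. The chaperone clusterin, Clu, fell (-1.34 ± 0.24, means 233 against 1049), as did the potassium channel Kcnj15 (-1.23 ± 0.24), and the zinc finger gene Zfp97 rose (1.19 ± 0.23) in the authors' deposited table. The remaining pair, the nucleoside carrier Slc28a2b (higher, means 22.6 against 2.27) and the protease Ctse (-1.16 ± 0.24), had means too low for the naming rule and were chosen after their values were seen, from the authors' deposited table. Esr1 (-0.10 ± 0.24), Adamts5 (-0.56 ± 0.24) and Ptgds (-0.31 ± 0.18) did not pass in the authors' deposited table. As groups, all 34 hepatocyte and visceral endoderm genes lay below 0 (median -0.33, 4 past the threshold adjusted over the list alone; adjusted p = 2.57e-18). Oxidative phosphorylation (median 0.24; adjusted p = 2.17e-11), ribosomal proteins (0.27; 1.11e-09) and the cell cycle (0.28; 6.98e-08) rose, and nutrient transporters fell (-0.17; 3.97e-04). Preeclampsia and angiogenic factors fell with an adjusted p = 0.0186, which became an adjusted p = 0.121 with a correlation of 0.05 and 0.126 without the length trend. Fold changes again fell with transcript length (rho = -0.38), and 14 genes passed after its removal, the 5 among them.

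**Figure D3:**
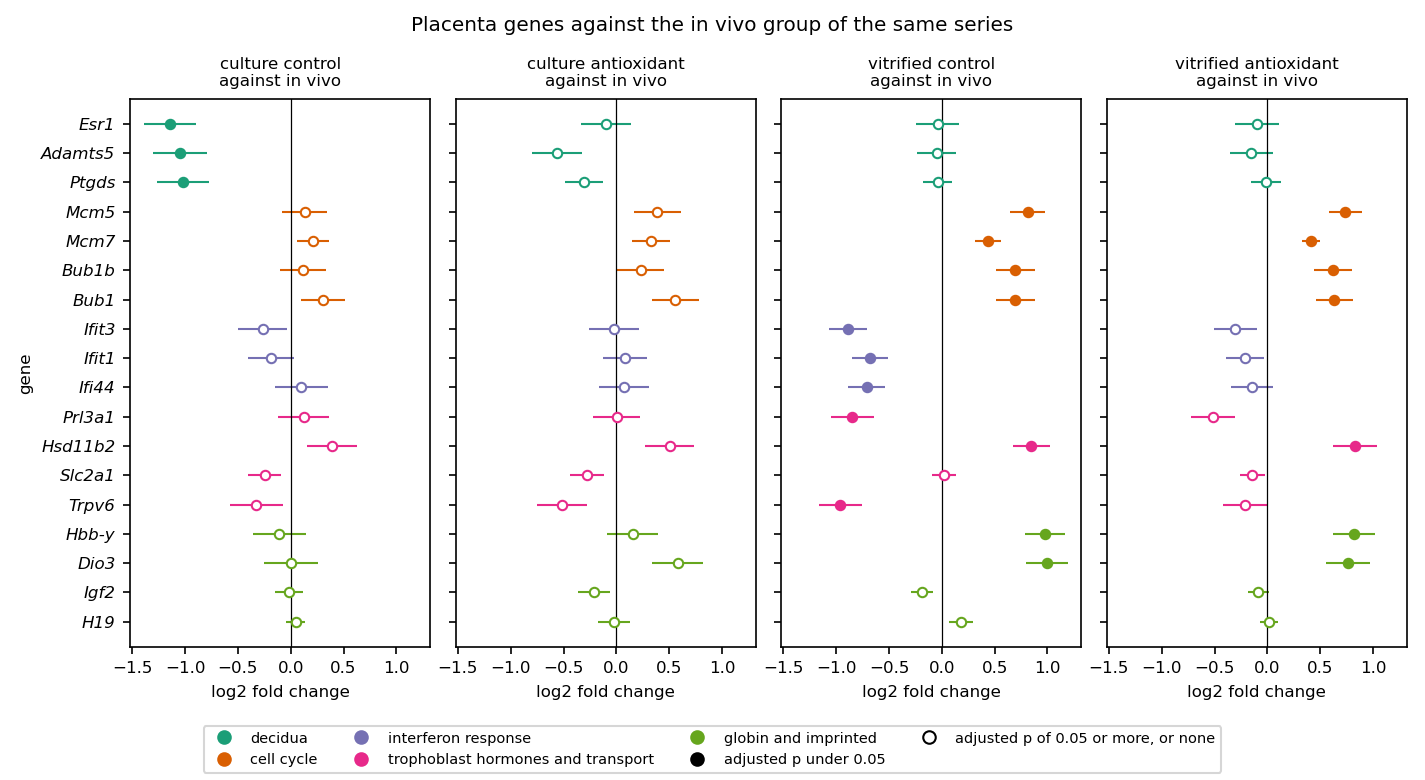
Deposited log2 fold change (x axis) of 18 placental genes in each of the 4 comparisons against the in vivo group of the same series, with bars of 1 standard error; filled points have an adjusted p under 0.05 and open points do not. The decidual gene Esr1 is at -1.15 in the culture control, and cell cycle genes such as Mcm5 (0.81 and 0.74) pass in both vitrified groups.

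Placentas from vitrified embryos expressed more cell cycle genes and fewer interferon response genes than in vivo placentas. Cell cycle genes rose in 6 of 38 members and fell in 0 (25 and 0 adjusted over the list alone; median 0.45; cameraPR adjusted p = 2.57e-29), including the helicase subunit Mcm5 (0.81 ± 0.17), the spindle checkpoint kinase Bub1b (0.70 ± 0.18) and cyclin Ccnb1 (0.70 ± 0.19) in the authors' deposited table. Interferon response genes fell in 5 of 35 (14 adjusted over the list alone; median -0.29; adjusted p = 6.34e-18), with the antiviral proteins Ifit3 at -0.89 ± 0.18, Ifi44 at -0.71 ± 0.18 and Ifit1 at -0.68 ± 0.17 in the authors' deposited table. All 9 measured mitochondrially encoded genes lay below 0 (2 past the threshold, 6 adjusted over the list alone; adjusted p = 5.81e-09). The imprinted deiodinase Dio3, which inactivates thyroid hormone (chromosome 12, 110279230 to 110281097, GRCm38), had means of 960 against 289 and 0.99 ± 0.20, and embryonic globin Hbb-y rose by 0.98 ± 0.19 in the authors' deposited table. Hsd11b2, which shields the fetus from maternal glucocorticoid, rose (0.85 ± 0.17), whereas the calcium channel Trpv6 (-0.96 ± 0.20), the lactogen relative Prl3a1 (-0.85 ± 0.20) and the basal keratin Krt14 (-0.86 ± 0.18) fell in the authors' deposited table. Mesenchyme and matrix genes fell (26 of 27 below 0, 1 past the threshold; adjusted p = 1.07e-05), as did hypoxia response genes (22 of 27 below 0, 1 past the threshold; adjusted p = 4.97e-05). In all, 216 genes passed (131 higher, 85 lower). The table gave no p for 256 genes that had a Wald score, among them 21 of the 34 hepatocyte and visceral endoderm genes, and the 13 left lay below 0 (adjusted p = 1.26e-07). With so many members left out as outliers, a few libraries may carry this fall. Cpt1a fell (-0.33 ± 0.09, adjusted p = 0.0297), while Igf2 (-0.19 ± 0.11) and Slc2a1 (0.02 ± 0.11) did not pass in the authors' deposited table.

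With antioxidants at vitrification, 206 placental genes differed from the same in vivo placentas (120 higher, 86 lower). Cell cycle genes rose again, in 4 of 38 members (24 adjusted over the list alone; median 0.39; adjusted p = 2.82e-24), with Mcm5 at 0.74 ± 0.16, Mcm7 at 0.42 ± 0.09 and Bub1 at 0.63 ± 0.17 in the authors' deposited table. The helicase Pif1 (1.04 ± 0.18) and Chaf1a, a subunit that loads histones behind the fork (0.54 ± 0.10), rose, and the gastrokine Gkn2 (-1.04 ± 0.21), the cobalamin carrier Tcn2 (-0.40 ± 0.07) and the amino acid transporter Slc7a8 (-0.51 ± 0.11) fell in the authors' deposited table. Placental hormones fell as a group with 0 members passing over all genes (4 adjusted over the list alone; 49 of 51 below 0; median -0.26; adjusted p = 1.61e-11). Mesenchyme and matrix genes fell in 2 of 27 (5 adjusted over the list alone; adjusted p = 4.38e-08), the basement membrane collagens Col4a1 (-0.36 ± 0.10) and Col4a2 (-0.38 ± 0.09) in the authors' deposited table. Macrophage genes fell (17 of 24 below 0, 9 down and 1 up adjusted over the list alone; adjusted p = 1.93e-04), as did decidual genes (23 of 24 below 0; adjusted p = 0.00209) and the 19 hepatocyte and visceral endoderm genes with a p (all below 0; adjusted p = 1.53e-04). Unfolded protein response genes (28 of 29 below 0; adjusted p = 3.01e-06) and hypoxia response genes (21 of 27 below 0; adjusted p = 1.02e-04) fell. Ifit3 stood at -0.30 ± 0.20 and Trpv6 at -0.21 ± 0.21, neither past the threshold, while Hbb-y (0.82 ± 0.20), Dio3 (0.76 ± 0.21) and Hsd11b2 (0.83 ± 0.21) passed in the authors' deposited table. The interferon list had an adjusted p = 0.00223, which became an adjusted p = 0.0559 with a correlation of 0.05.

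The direct comparison of the 2 control groups crossed the series, so it set vitrification and culture side by side but also the 2 series. In liver, vitrified embryos gave lower levels of short transcripts for mitochondria and ribosomes and higher levels of many long ones. Oxidative phosphorylation fell in 36 of 52 members and rose in 1 (42 and 2 adjusted over the list alone; median -0.45; adjusted p = 1.01e-16), ribosomal proteins fell in 25 of 41 (28 adjusted over the list alone; adjusted p = 2.95e-12), and mitochondrially encoded genes fell in 7 of 12 (7 adjusted over the list alone; median -0.85; adjusted p = 2.7e-09). Ptch1 (1.99 ± 0.16, means 434 against 94.7), Gpam (1.53 ± 0.14) and Lmbrd2 (2.05 ± 0.20) rose most clearly in the authors' deposited table. The paternally expressed zinc finger gene Peg3 rose (1.33 ± 0.19), and the platelet receptor subunit Gp9 (-0.92 ± 0.17), the peroxiredoxin Prdx5 (-0.67 ± 0.12) and mt-Nd4 (-1.14 ± 0.15) fell in the authors' deposited table. Antioxidant enzymes fell in 25 of 46 and rose in 2 (30 and 2 adjusted over the list alone; adjusted p = 3.99e-08), and megakaryocyte and platelet genes fell in 8 of 16 (adjusted p = 0.00115), while cholangiocyte genes rose in 4 of 11 (5 adjusted over the list alone; adjusted p = 0.00633). The comparison gave 4618 genes (2274 higher, 2344 lower). At an absolute log2 fold change of 1 or more, 151 of 166 were higher. The median fold change rose by 0.66 from the shortest to the longest of 10 equal groups of transcripts (rho = 0.55), and 47.1% of the called genes with a transcript stayed called once that trend was removed. The removal ended the macrophage call (adjusted p = 1.06e-04, then 0.105).

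In placenta the same comparison gave 2065 genes (1105 higher, 960 lower). At an absolute log2 fold change of 1 or more, 30 of 38 were higher. The sterol carrier Stard4 (1.09 ± 0.13), the transcription factor Sox4 (0.74 ± 0.09), the phosphatase Dusp4 (1.24 ± 0.17) and Inhba (1.25 ± 0.24) rose, and Slc2a1 rose by 0.45 ± 0.11 in the authors' deposited table. Mitochondrially encoded genes fell in 8 of 9 members (8 adjusted over the list alone; median -0.65; adjusted p = 3.96e-09), with mt-Nd2 at -0.84 ± 0.17, and the imprinted gene Nnat fell (-1.13 ± 0.24) in the authors' deposited table. Hepatocyte and visceral endoderm genes fell (33 of 34 below 0, 2 past the threshold; adjusted p = 2.09e-04), and macrophage genes rose in 2 of 23 (adjusted p = 0.0266, and adjusted p = 0.187 with a correlation of 0.05). Oxidative phosphorylation fell in 8 of 52 (17 adjusted over the list alone; adjusted p = 1.4e-07), and that call ended with the length trend removed (adjusted p = 0.058). Fold changes rose with transcript length here too (rho = 0.47), and 41.9% of called genes stayed called after its removal, against 47.1% in liver. Antioxidant enzymes fell in 9 of 47 (adjusted p = 9.85e-04), a call that ended with a correlation of 0.05 (adjusted p = 0.0834) and without the length trend (adjusted p = 0.172).

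**Figure D4:**
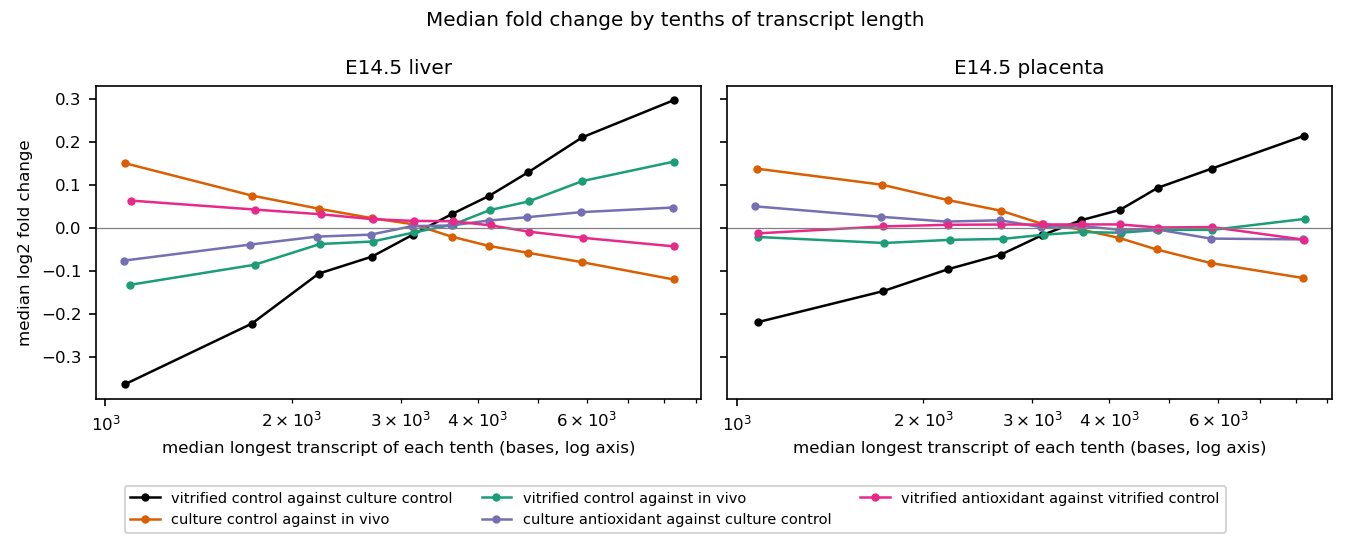
Median deposited log2 fold change (y axis) of genes in 10 equal groups by transcript length (x axis, bases, log scale) for 5 comparisons in liver (left) and placenta (right). The vitrified control against the culture control runs from -0.36 to 0.30 in liver and from -0.22 to 0.21 in placenta, the steepest of the lines drawn.

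Whether the 2 treatments moved the same genes was tested on the differences themselves. The departure from in vivo differed between vitrified and culture controls at 2125 liver genes (1196 higher and 929 lower after vitrification). With an empirical null the count was 232 (196 higher, 36 lower), and without the length trend 1215 (703 higher, 512 lower). Ptch1 was at -1.94 after culture and 0.26 after vitrification, a difference of 2.20 ± 0.23 (Benjamini-Hochberg adjusted p = 1.83e-17), and Gpam differed by 1.57 ± 0.21. Gypa differed by -0.70 ± 0.12 and the stress transcription factor Ddit3 by -0.80 ± 0.14. In placenta 19 genes differed, among them Tdo2 (1.60 ± 0.31), Dusp4 (1.09 ± 0.25) and, in the other direction, the imprinted G protein subunit gene Gnas (-0.55 ± 0.11) and Actg2 (-1.35 ± 0.29). With an empirical null the placental count was 11. In simulated tables the test recovered 35.5% of differences from in vivo of 0.5 in liver and 22.5% in placenta. The antioxidant effect differed between the series at 0 genes in liver and 0 in placenta. At an unadjusted p under 0.05, by the z test used here, there were 978 of 19814 in liver and 684 of 20748 in placenta. Neither share is above what that threshold gives by chance alone. Over genes with a mean of 10 or more in both comparisons, there were 903 of 13969 in liver and 567 of 14443 in placenta. The liver share was then above that level and the placental share was not, and genes are not independent. Closest were Pdk4 in liver (-0.62 ± 0.16, adjusted p = 0.597) and Meg3 in placenta (1.03 ± 0.27, adjusted p = 1.00). In simulated tables with the errors and priors of the antioxidant comparisons, this test recovered 65.5% of differences of 1 planted before shrinkage in liver and 53% in placenta, and 17.5% and 7% of differences of 0.5. Across genes, which are not independent replicates, antioxidant effects in the series had a Pearson r of -0.139 in liver (Spearman rho = -0.168) and -0.001 in placenta (0.019), and departures from in vivo had 0.140 in liver (0.134) and 0.225 in placenta (0.201). Once length trends were removed, the liver antioxidant value moved to -0.056 and the liver departure value to 0.268.

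Control and antioxidant groups of one series were compared with the same in vivo libraries, so their calls overlap in part by construction. In liver, 1510 genes passed in the same direction in both culture comparisons, 0 in opposite directions, against 242 for independent lists of those sizes and a mean of 707 (highest 762) in 100 simulated sets with no effect that shared the in vivo libraries and took lists of the same sizes. The vitrification comparisons shared 739 genes, against 71.2 and 303 (highest 340). In placenta the comparisons shared 60 genes in the vitrification series, against 1.51 and 34.1 (highest 45). They shared 2 in the culture series, against 0.068 and 1.35 (highest 4). These 2 lay within the range of simulated lists forced to those sizes. Called by an adjusted p under 0.05 in place of a fixed size, the simulated sets for the culture series shared a mean of 0 genes. Splitting the in vivo libraries, to give each comparison its own, was not possible without values per library.

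Of 413 list tests, 152 passed, and a few lists passed in none of the comparisons. The lipoate-dependent complexes, which carry one of the supplements as a cofactor, had a smallest adjusted p of 0.11 (vitrified control liver against in vivo). The smallest was 0.116 for p53 targets and apoptosis, 0.0514 for labyrinth trophoblast and 0.543 for the sex-linked control genes. Of the genes set for reporting everywhere, Igf2 and H19, which share an imprinted domain, and Nqo1 passed in none of the 14 comparisons. In the authors' deposited tables Igf2 ran from -0.21 ± 0.15 (placenta, culture antioxidant against in vivo) to 0.10 ± 0.09 (placenta, vitrified antioxidant against vitrified control). H19 ran from -0.27 ± 0.10 (liver, vitrified antioxidant against in vivo) to 0.18 ± 0.11 (placenta, vitrified control against in vivo) in the authors' deposited tables. Cpt1a also fell in placenta of the vitrified antioxidant group against in vivo (-0.34 ± 0.10, adjusted p = 0.0439), per the authors' deposited table. Neither Xist nor the Y-linked Ddx3y passed in any comparison of the authors' deposited tables. Each group mixed males and females, which widens the spread of these genes. Neither this nor the list value tests whether the sexes were balanced.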

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

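The tests of length and GC content named in this section were written before their values were seen; those of the in vivo share, hepatocyte share, delayed development and decidual tissue were chosen only after the result was seen.

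Lower hepatocyte, erythroid and macrophage transcripts in liver of the vitrified control against in vivo had a few possible sources. A trend with transcript length is unlikely, since the largest adjusted p of the 3 lists after its removal was 2.54e-13. A smaller share of hepatocytes alone would leave the macrophage list level or raised, and its median log2 fold change was -0.49. That fall was part of the pattern and known before the rule was chosen, so this was no independent test. It shows only that a smaller hepatocyte share alone does not account for the macrophage fall. Mesenchyme and endothelial genes rose in the same comparison, and the share of hepatocytes was not measured. Delayed development could fit: 7 of 8 predicted globin directions were met (Hbb-y, Hba-x and Hbb-bh1 higher and Hbb-bs lower, in each tissue), the exception being Hbb-bh1 in liver with means of 2117 against 2137, but several of the 7 had no passing p and the series holds no earlier stage to compare. This test cannot tell delay from a direct effect of vitrification.

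Lower decidual transcripts in placenta of the culture control, such as Prl8a2 with means of 6889 against 28834, might reflect a trend with length or less decidua in the tissue taken. The list kept an adjusted p of 4.42e-08 with the length trend removed, so length is unlikely. Less decidual tissue was predicted to lower at least 75% of the members, and no such loss fewer than 50%; the value was 72% (18 of 25), so the test cannot tell. An earlier form of that prediction used the most abundant member, Krt8, a keratin that trophoblast also makes, whose log2 ratio was 0.26, and it was revised after that was seen. The median log2 ratio of the 25 members was -1.22. Of the 18 lower members, 14 were nearer to in vivo with antioxidants in culture and 4 were further from it. Group means do not separate less decidua from lower expression within it, so whether the placentas held less decidua was not settled.

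The departure from in vivo differed between vitrified and culture controls at 2125 liver genes and 19 placental genes by a test of the difference itself, which marked both for a closer look. For the direct comparison of these controls, a length trend could account for part: 47.1% of called liver genes and 41.9% of placental genes stayed called after its removal, which cannot tell. GC content was unlikely as the main source, since 71.0% and 91.1% stayed called. The median in vivo share of the control log2 ratio was 0.165 in liver and 0.159 in placenta. That spoke against a gap shared by the in vivo groups as the main source. The genes were picked by their control difference, which lowers the share, and 65.5% in liver and 77.4% in placenta had the same direction in vivo. A gap between the series in the cultured embryos alone would not show in this test.

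A single library stood far from the other 5 of its group in size factor in 2 of 12 groups, with 1.496 for liver in vivo of the culture series and 1.53 for placenta culture antioxidant, and chance marks about 1 in 20 groups.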

How the results depend on the processing

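Alternatives with transcript length or GC content, fold changes without the prior and lists with outlier genes were chosen only after the result was seen, the others beforehand. No list call or named gene call passed in the opposite direction under an alternative. Turns of direction among the other called genes were not tallied. Counts of genes are given in the order liver vitrified against culture control, then liver culture control, culture antioxidant, vitrified control and vitrified antioxidant against in vivo. An adjusted p under 0.01 left 3038, 2366, 799, 990 and 330, an absolute log2 fold change of 1 or more left 166, 131, 14, 21 and 15, and an empirical null left 1, 148, 4, 3 and 1. Without the length trend the first count was 2774, of which 690 were called only then. In placenta, an adjusted p under 0.01 left 2 for the vitrified antioxidant against its control, 925 between controls, 152 for the culture control, 67 for the vitrified control and 17 for the vitrified antioxidant against in vivo; a fold change of 1 or more left 0, 38, 49, 1 and 2, and an empirical null left 1, 1, 0, 32 and 0. The culture antioxidant placenta went to 0 with the empirical null and 14 without the length trend, and the count between placental controls without it was 1072, of which 256 were called only then. The 3 antioxidant comparisons with 0 genes stayed at 0 in all alternatives. Fewer genes passing follows from a stricter threshold, and for the other changes the cause was not tested. The 2125 liver differences became 232 with an empirical null and 1215 without length, and the 19 in placenta 11 with an empirical null and 11 without the prior. The correlation of antioxidant effects in liver was -0.221 over means of 100 or more, -0.119 with no minimum, -0.165 on Wald scores and -0.056 without length, and in placenta, where it was -0.001 in the main analysis, 0.057 over means of 100 or more, -0.013 with no minimum, 0.012 on Wald scores and 0.007 without length, so its sign was not settled. That of departures from in vivo in liver was 0.119 over means of 100 or more, 0.119 on Wald scores and 0.268 without length, and in placenta 0.204 with no minimum, 0.180 on Wald scores and 0.270 without length. Overlaps were 668 in liver culture, 230 in liver vitrification and 8 in placenta vitrification at 0.01, and 1235, 5 and 122 at 0.1 in liver vitrification, placenta culture and placenta vitrification. Counts of lists at a correlation of 0.05 went to 6 and 6 for the liver antioxidant comparisons in culture and vitrification, 3 for liver culture antioxidant against in vivo, 6 for placental antioxidants in culture, 3 between placental controls, and 4, 5 and 8 for placental culture control, culture antioxidant and vitrified control against in vivo. Without length, lists went to 6 for liver antioxidants in culture and 6 between liver controls, and with a background of means of 10 or more to 5 for the liver culture control against in vivo. Of 152 list calls 99 held at a correlation of 0.05, 116 without length, 143 by ranks and 151 with outlier genes. Of the named calls, 578 held and 26 did not with adjustment over every gene, 463 at 0.01, 87 with a fold change of 1 or more, 511 without length, 584 without GC content and 56 with an empirical null. Of the counts of genes, lists and overlaps not given here, the totals stayed within 1.5 times the main one, but their splits by direction could move further, as from 902 to 468 higher genes for the vitrified control liver and from 407 to 238 for the vitrified antioxidant liver without length. Per comparison, 24 counts of named genes moved further. No paired analysis was possible because no label ties a library of one group to one of another and values per library were not used here. For lack of such values, DESeq2 and edgeR refits, a refit with no low-count filter, leave-one-out fits, a sex covariate, a replicate block, and fits without the libraries that stood apart were not run. Depth (group mean totals of 20.5 to 28.9 in units of 1e6 normalized reads) limits genes with few reads.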

Other observations

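The slope tests in this section were written before their values were seen, and the comparison of the in vivo groups was chosen only after the result was seen.

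Genes of the visceral endoderm differed widely in group mean in the placenta of vitrified embryos, but the tables gave many of them no p. Alpha-fetoprotein Afp had computed means of 19153 in the vitrified control against 146048 in vivo, apolipoprotein Apoa1 2093 against 16862, transthyretin Ttr 1078 against 5338 and albumin Alb 403 against 4794. With antioxidants at vitrification Apoa1 had 4791 against 17781 and Alb 955 against 5055. In the same comparisons 21 and 15 of the 34 list members had a Wald score but no p in the authors' deposited table. DESeq2 leaves out a p where single libraries stand out. The gaps in group mean may therefore rest on a single library or a few, which could not be seen without values per library.

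The in vivo livers of the 2 series differed from each other at 1075 genes (615 higher and 460 lower in the vitrification series) by a test made from the deposited statistics, and the in vivo placentas at 0. In placenta that test had less power: between the controls it called 829 of the 1954 genes the deposited table called, against 4126 of 4431 in liver. The golgin Tmf1 (1.03), the DNA repair factor Rbbp8 (0.45) and the condensin subunit Smc4 (0.59) were higher in log2 ratio, and the deacetylase Hdac7 (-0.56) was lower. Of genes called between the liver controls, 340 (7.67%) were called in the same direction between the in vivo livers, against 184 of independent lists. Xist, the X-inactivation RNA, had group means of 6012 in vitrified control livers against 2339 with antioxidants, and 2111 against 1105 in the culture series, although the labels give 3 females per group.

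Fewer genes differed from in vivo with antioxidants than without, a count that also depends on the standard errors. One hypothesis was that antioxidants moved expression toward in vivo. The slope of the antioxidant change on the gap to in vivo, with shared error subtracted, was predicted to lie above 0.25 with and without the length trend if so, and under 0.1 in both if not. In the culture series it was 0.225 in liver (0.181 without the length trend) and 0.0843 in placenta (0.149 without it), between the limits in at least 1 form, so the test cannot tell. In the vitrification series it was -0.0544 in liver (-0.207 without the length trend) and -0.0873 in placenta (-0.0976 without it), under 0.1 in both forms. Before the subtraction the slopes were 0.158 in liver and 0.268 in placenta (0.297 and 0.279 in the culture series). The error covariance subtracted, 0.01525 and 0.01678, exceeded the whole covariance seen, 0.01249 and 0.01496. No error of the slope was computed, so the hypothesis was not met but cannot be excluded.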
